A study of Mus musculus with 4 samples.

How the data were processed

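RNA from sorted mouse bone marrow LSK cells was measured on 4 single-colour arrays, 1 each for wild-type native, Sf3b1+/- native, wild-type transplanted and Sf3b1+/- transplanted cells. Per the labels, cells were stained and sorted by flow cytometry, total RNA was column-purified, and 20 ng of it was mixed with spike-in transcripts of known amounts, amplified and labelled with Cy3. Per the file headers, the arrays were of Agilent design 028005, read with Feature Extraction 10.7.1.1 under protocol GE1_107_Sep09, with probe positions on mouse build mm9. Neither the labels nor the file headers say how many mice were pooled for an array, so the mice counted in the labels are not used as replicates.

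The deposited scanner files hold spot intensity values: per the file headers, the processed signal is the spot intensity after the scanner software's background subtraction and detrending within the array, with no scaling between arrays. The deposited series table holds ratio values, and from the values themselves each is the linear processed signal divided by 1 constant per array, so that the 75th percentile of each column is about 1.00 while the column medians are 0.0810, 0.0745, 0.0816 and 0.0747. On the log2 scale these ratio values and the processed signal correlated with r of 1.00 on each array. The values are not centred on a median and are not differences between samples; a larger value means more signal. The tool the authors used for this step is not given in the sources used here.

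Each array held 59305 non-control spots and 3671 control spots. The spots represent 55681 distinct probes, of which 27509 matched a gene symbol through the RefSeq names of the mouse assembly GRCm38.p6, used for names alone, and 28172 did not, among them 16194 probes named by genome position. The named probes represent 20886 genes. Replicate spots of a probe were averaged on the log2 scale, and the probe with the highest mean normalized signal stood for its gene. Other probes of a named gene were compared with it, and those of Kdr and Uhrf1 pointed the other way in at least 1 comparison. Probes of multi-gene families such as Ear, Klra, Bcl2a1, Clca3a and the alpha-globins may read more than 1 member.

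The log2 processed signal was shifted on each array by its 75th percentile. The plan took this percentile over all probes unless the mean share of detected spots was under 50%; the share was 49.5%, so probes well above background on all 4 arrays were used and the percentile over all probes became an alternative. Well above background is the scanner software's call. Compared genes were well above background on at least 2 of the 4 arrays, which left 13033 genes, of which 12175 passed on all 4 arrays; 7268 genes passed on none. The 75th percentile of the signal before scaling was 253, 299.7, 292 and 430.3 units for wild-type native, Sf3b1+/- native, wild-type transplanted and Sf3b1+/- transplanted cells, against a median local background of 43, 45, 44 and 42. No spot was saturated, and 113, 121, 125 and 112 spots were marked as outliers by the scanner software. Per the file headers, the slope of log signal on log spike-in amount was 1.02, 1.01, 0.997 and 0.990, with r squared from 0.978 to 0.986. Relative to the spike-ins the signal was 1.19-fold, 1.40-fold and 2.00-fold that of wild-type native cells in Sf3b1+/- native, wild-type transplanted and Sf3b1+/- transplanted cells. The number of arrays, 1 per group, limits the precision. All 4 arrays lay on 1 slide with 1 scan time, so there is no batch of slide or scan to separate, and the position on the slide follows the group. Batches of sorting, RNA preparation or labelling were not tested. With 1 array per group they could not be told apart from the group.

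Groups came from the labels. Within each setting the difference Sf3b1+/- minus wild type was computed per gene without a test, and genes at least 2-fold apart were counted. Genes at least 1.5-fold apart in the same direction in both settings were counted beside the number that independent lists would share, with Pearson's r and Spearman's rho across genes. Genotype and setting were tested in 1 additive model with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg 0.05), which has 1 residual degree of freedom per gene and a prior of 3.04 degrees of freedom. The residual of that model is the genotype-by-setting contrast. The R package data.table, version 1.17.8, read the files. The p-values measure spread between these arrays, which may be technical. Tested on simulated data for 13033 genes with 200 changed, the fit recovered 1% of 2-fold and 91% of 4-fold changes after adjustment. At an unadjusted p under 0.05 it recovered 98% and 99%, with 100% in the right direction. Of the unchanged genes 10 were called and 5.19% had an unadjusted p under 0.05. The simulated noise was independent between genes and arrays, with variances from limma's fitted prior and no setting or genotype-by-setting effect. These rates therefore hold under the model's own assumptions and do not show how the fit behaves on the real arrays.

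A set of 29 gene lists, the thresholds, the tests and the rule for naming genes were fixed before the data were examined. The lists cover SF3b and U2 proteins, other splicing factors, nonsense-mediated decay, stem cells, genes higher in old stem cells, lymphoid-primed and granulocyte-monocyte progenitors, megakaryocytes, erythroid cells, neutrophils, B and plasma cells, T and NK cells, macrophages and dendritic cells, mast cells with basophils and eosinophils, stroma and endothelium, S phase, G2 and M phase, cyclin-dependent kinase inhibitors, p53 targets, the integrated stress and unfolded protein response, heme and iron, polycomb, Hox, interferon response, immediate early and heat shock, antioxidant and FoxO targets, ribosomal proteins, the respiratory chain and sex-linked genes. Each list is described by the median difference of its compared genes, relative to the median of all compared genes, and by its percentile among 10000 random lists of equal size drawn from 20 bins of matched signal. These percentiles are a description and not a test over animals. Some lists overlap: 3 genes, Vwf, Selp and Itgb3, are in both the megakaryocyte and the old stem cell list, 1, Slamf1, is in both stem cell lists, and 2, Hoxb5 and Hoxa9, are in the stem cell and Hox lists.

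Single genes are named by rule. Named are Sf3b1, the 12 highest and 12 lowest genes over both settings by the smaller of their absolute differences, the 5 highest and 5 lowest in each setting, the 10 highest and 10 lowest for the setting, the 5 largest bounds per direction, and up to 4 members of each list with the largest mean difference, all on genes well above background on all 4 arrays except the bounds. Key genes of splicing and cell cycle inhibition may be named regardless of rank. Fcmr, Ebf1 and Gpr183 lie outside this rule and are named after their values were seen, because they stand in small counts. Genes well above background on both arrays of 1 genotype and on neither of the other are given as bounds: the signal is divided by the lowest signal called well above background on the other genotype's array, or by the gene's own signal there if that is higher, and the smaller bound of both settings is printed.

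Alternatives planned before the data were examined were quantile normalization, normexp background correction with an offset of 50 followed by quantile normalization, the 75th percentile over all probes, spike-in scaling, the deposited series table, a filter on all 4 arrays, no filter, the median over a gene's probes, thresholds of 1.5-fold in 1 setting and 2-fold in both, limma with a variance trend or robust settings, models with genotype alone or setting alone, and leaving out 1 array. Cyclic loess and the use of every probe as its own feature were added later. Normexp used the median spot signal where the plan had named the mean, because the median is the spot signal these scanner files give beside the processed one. Leaving out an array leaves 1 setting and no residual degree of freedom, so it gives a value without a test. Control spots were left out except for the spike-ins, and 0 sample columns in the deposited values were left unused. Splicing was not analysed here.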

Results

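Gene expression was profiled in LSK cells, the lineage-negative, c-Kit-positive and Sca-1-positive bone marrow fraction that holds hematopoietic stem cells and multipotent progenitors. The cells came from wild-type C57BL/6 mice and from mice with a single functional copy of Sf3b1 (Sf3b1+/-), since embryos without any functional copy die before implantation. Sf3b1 encodes the largest subunit of SF3b, the part of the U2 small nuclear ribonucleoprotein that contacts the intron branch site, and the human gene is recurrently mutated in myelodysplastic syndromes. Native LSK cells were taken from mice aged 20 weeks. Transplanted LSK cells were donor cells recovered 9 months after marrow of either genotype had been given to irradiated hosts, a step that per the labels serves to rule out indirect effects of the marrow environment. The labels give 4 mice for the native collection and 5 recipients for the transplanted one, and how many mice stand behind each array is not given in the sources used here.

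Each of the 4 groups was measured on 1 single-colour array, so no difference within a setting has a replicate check and none carries a p-value. All 4 arrays lay on 1 slide and were scanned in 1 run, so the place on the slide cannot be told apart from the group. The share of spots well above background was 47.7% for wild-type native cells, 48.7% for Sf3b1+/- native cells, 50.2% for wild-type transplanted cells and 51.5% for Sf3b1+/- transplanted cells. Replicate spots of 1 probe differed by an SD of 0.069 to 0.084 on the log2 scale. Among 20886 genes with a symbol, 13033 were well above background on at least 2 arrays and were compared. All differences are on the log2 scale after scaling each array to the 75th percentile of its detected probes, and Sf3b1+/- minus wild type unless another direction is named. Against the RNA spike-ins the median of all compared genes lay 0.25 higher in Sf3b1+/- than in wild-type native cells and 0.51 higher in transplanted cells, so the values below describe each gene relative to the bulk of its array.

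Sf3b1 itself (NM_031179) was measured by 1 probe, well above background on all 4 arrays. Its signal in Sf3b1+/- cells was 75.4% of wild type in native cells and 92.8% in transplanted cells, which are log2 differences of -0.41 and -0.11. With spike-in scaling these differences were -0.15 and 0.40, below the shift of all genes in both settings. The labels do not say which part of Sf3b1 is deleted, so whether this probe can read the loss is open. The proteins of SF3b and the U2 particle, Sf3b1 included, showed no joint shift: the median over 14 measured genes was -0.01 in native cells, at percentile 61.6 of 10000 random lists of equal size and signal, and 0.01 at percentile 69.8 in transplanted cells. Within that group Sf3b3 (0.48 and 0.44) and Sf3b2 (0.25 and 0.47) were higher in both settings, whereas Sf3b6 (-0.31 and -0.74) and Snrpb2 (-0.17 and -0.41) were lower. Other splicing factors mutated in myeloid disease had medians of 0.11 (percentile 98.6) and 0.02 (percentile 73.9), with Prpf40b at 0.50 and 0.69 and Ddx41 at 0.18 and 0.67. Factors of nonsense-mediated decay, which degrades transcripts with premature stop codons, stood at 0.02 (percentile 49.7) and 0.12 (percentile 81.0), with Rnps1 at 0.18 and 0.59.

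The first comparison asks how native LSK cells of Sf3b1+/- mice differ from wild type. Genes of the early B lineage were lower in native Sf3b1+/- cells. The surrogate light chain genes Vpreb1, Igll1 and Vpreb3, which early B-cell precursors use before they have an immunoglobulin light chain, were lower by 4.49-fold, 4.30-fold and 4.15-fold. The 10 measured B cell and plasma cell genes had a median of -1.27, below every one of the 10000 random lists. Of these genes 6 were at least 1.5-fold lower and 1 was at least 1.5-fold higher. Only 6 of the 10 were well above background on all 4 arrays, and among those Cd22 stood at -0.14 and Jchain at 0.27. With normexp the list median was -0.62 in native and -0.30 in transplanted cells, at percentiles 0 and 0.08. Megakaryocyte genes went the other way, with a median of 0.48 over 15 genes, above all random lists. Ppbp (NM_023785), a platelet chemokine, was 2.85-fold higher, and Gp1ba (NM_010326) and Gp5, subunits of the platelet receptor for von Willebrand factor, were 2.19-fold and 1.85-fold higher.

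Several other gene groups of native cells stood apart from random lists. Erythroid genes had a median of 0.27 (percentile 99.9), with Hba-a2 at 0.93, Klf1, a master regulator of red cell genes, at 0.90, Hba-a1 at 0.75 and the erythropoietin receptor gene Epor at 0.50. The alpha-globin genes Hba-a1 and Hba-a2 are near-identical copies, so their probes may read both. Mast cell, basophil and eosinophil genes had a median of 0.28 (percentile 99.9; 0.16 with normexp), with the eosinophil peroxidase gene Epx at 1.16. G2 and M phase genes had a median of 0.16, above all random lists, with Ttk at 0.71 and Plk1 at 0.42, and S phase genes a median of 0.05 (percentile 98.4), with Chaf1a at 0.25. Immediate early and heat shock genes, which respond within minutes to stimulation or stress, had a median of -0.27, below all random lists (-0.14 with quantile normalization), with Fosl2 at -1.68 and Klf6 at -0.68, while Egr2 at 0.79 and Dusp1 at 0.70 were higher. T and NK cell genes (-0.28, percentile 0.06), macrophage and dendritic cell genes (-0.24, percentile 0.64), p53 target genes (-0.15, percentile 0.34) and interferon response genes (-0.11, percentile 1.09) were lower. Among their members the interleukin-2 receptor gene Il2rb stood at -1.27, Csf1r at -0.50, Tnfrsf10b at -0.62 and Ifi27l2a at -0.95, while the p53 targets Gdf15 (1.07), Zmat3 (0.99) and Phlda3 (0.37) were higher. Over the 12 T and NK cell genes well above background on all 4 arrays the median was -0.15.

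The native genes furthest apart were not all members of these groups. Lrmda was 12.2-fold higher in native Sf3b1+/- cells and 1.21-fold higher in transplanted ones, and Rftn2 was 3.93-fold and 1.51-fold higher. Ptpro, a receptor-type tyrosine phosphatase, was 4.41-fold lower in native and 1.47-fold lower in transplanted cells, and Zfp958 was 4.06-fold and 1.22-fold lower. At least 2-fold apart in native cells were 102 genes higher and 175 lower in Sf3b1+/-. That split depends on the scaling, with 139 higher and 155 lower after quantile normalization, 8 and 25 after normexp background correction, and 242 and 91 with spike-in scaling.

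The second comparison asks the same of donor LSK cells that had regenerated in wild-type surroundings for 9 months. Stem cell genes were higher in transplanted Sf3b1+/- cells. Of 23 measured hematopoietic stem cell genes 13 were at least 1.5-fold higher and 1 was at least 1.5-fold lower, and their median was 0.62, above all random lists, against 0.02 (percentile 72.7) in native cells. Hoxb5 was 2.65-fold, Slamf1, which encodes the stem cell marker CD150, 2.54-fold, and Tek, which encodes the angiopoietin receptor, 2.39-fold higher. Genes known to be higher in hematopoietic stem cells of old mice had the largest list median, 1.13, with 19 of 23 genes at least 1.5-fold higher, against 0.07 (percentile 88.1) in native cells. Among these Vwf was 3.54-fold, Nupr1 2.98-fold, Ehd3 2.89-fold and Clu 2.51-fold higher.

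Hox genes had a median of 0.48 (percentile 99.9) over 17 genes in transplanted cells, 0.36 over those well above background on all 4 arrays, and -0.14 when Hox genes close to background were included. The members measured on all 4 arrays with the largest differences were from the Hoxb cluster, with Hoxb6 at 2.09, Hoxb2 at 1.58 and Hoxb5 at 1.41. Megakaryocyte genes were higher again (median 0.89, above all random lists), with 10 of 15 at least 1.5-fold higher. In the opposite direction, lymphoid-primed progenitor genes had a median of -0.43 (percentile 0.02) in transplanted cells, against 0.07 (percentile 92.6) in native ones. The interleukin-7 receptor gene Il7r, required for lymphoid development, stood at -1.33, Blnk, an adaptor of B-cell receptor signalling, at -1.14, and Dntt, which adds nucleotides at antigen receptor junctions, at -0.99. B cell and plasma cell genes (-0.64, below all random lists), T and NK cell genes (-0.54, below all) and neutrophil genes (-0.44, percentile 0.03, and -0.26 with normexp) were lower too, the last with Chil3 at -1.42, Camp at -1.27 and S100a8 at -1.25.

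Genes of protein synthesis and respiration were slightly lower in transplanted Sf3b1+/- cells. Mitochondrial respiratory chain genes had a median of -0.28 over 86 genes, below all random lists, with Atp5e at -0.88 and Ndufb3 at -0.77, against -0.10 (percentile 29.2) in native cells. The native list lay lower among random lists under other scalings, at -0.07 (percentile 1.11) with cyclic loess, -0.07 (percentile 0.23) with quantile normalization and -0.05 (percentile 1.58) with normexp. Ribosomal protein genes had medians of -0.22 in native and -0.42 in transplanted cells, both below all random lists, with 75 of 78 genes negative in both settings, yet quantile normalization gave -0.04 (percentile 27.6) and -0.08 (percentile 29.5), normexp -0.03 and -0.04, and cyclic loess -0.07 and -0.22. The p53 target genes (0.24, percentile 99.7), interferon response genes (0.20, percentile 99.3) and immediate early and heat shock genes (0.11, percentile 99.97) were higher in transplanted cells, with Phlda3 at 1.31, Oas3 at 0.81 and Egr2 at 0.57, while Tnfrsf10b (-0.47), Ifi27l2a (-0.65), Irf1 (-0.42), Fosl2 (-0.44) and Klf6 (-0.31) were lower. G2 and M phase genes had a median of 0.15 (percentile 98.7). Erythroid genes (0.08, percentile 66.5), mast cell, basophil and eosinophil genes (0.10, percentile 70.8, and -0.04 after normexp), macrophage and dendritic cell genes (-0.04, percentile 56.3) and S phase genes (0.04, percentile 89.8) lay within the central 95% of random lists. The 3 measured Y-linked genes, Ddx3y (-0.13 and -0.30), Eif2s3y (-0.36 and -0.61) and Uty (0.35 and -0.70), were seen on all 4 arrays, with a list median of -0.12 (percentile 17.6) in native and -0.61 (percentile 0.61) in transplanted cells.

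The largest single differences of transplanted cells were in Ramp2 (10.9-fold higher), a co-receptor of adrenomedullin, the potassium channel gene Kcnj5 (7.50-fold), Islr (6.00-fold), Arc (5.72-fold) and Ccn1 (5.12-fold). Lower were Rps4l (4.25-fold), Bhlha9 (3.75-fold), Wfdc18 (3.72-fold), the lymphoid transcription factor gene Ikzf3 (3.36-fold) and Tnfsf11, which encodes the osteoclast factor RANKL (3.05-fold). In all 268 genes were at least 2-fold higher and 168 at least 2-fold lower. The split was 334 and 123 after quantile normalization, 362 and 118 after cyclic loess, 91 and 24 after normexp, and 1416 and 28 with spike-in scaling.

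**Figure D1:**
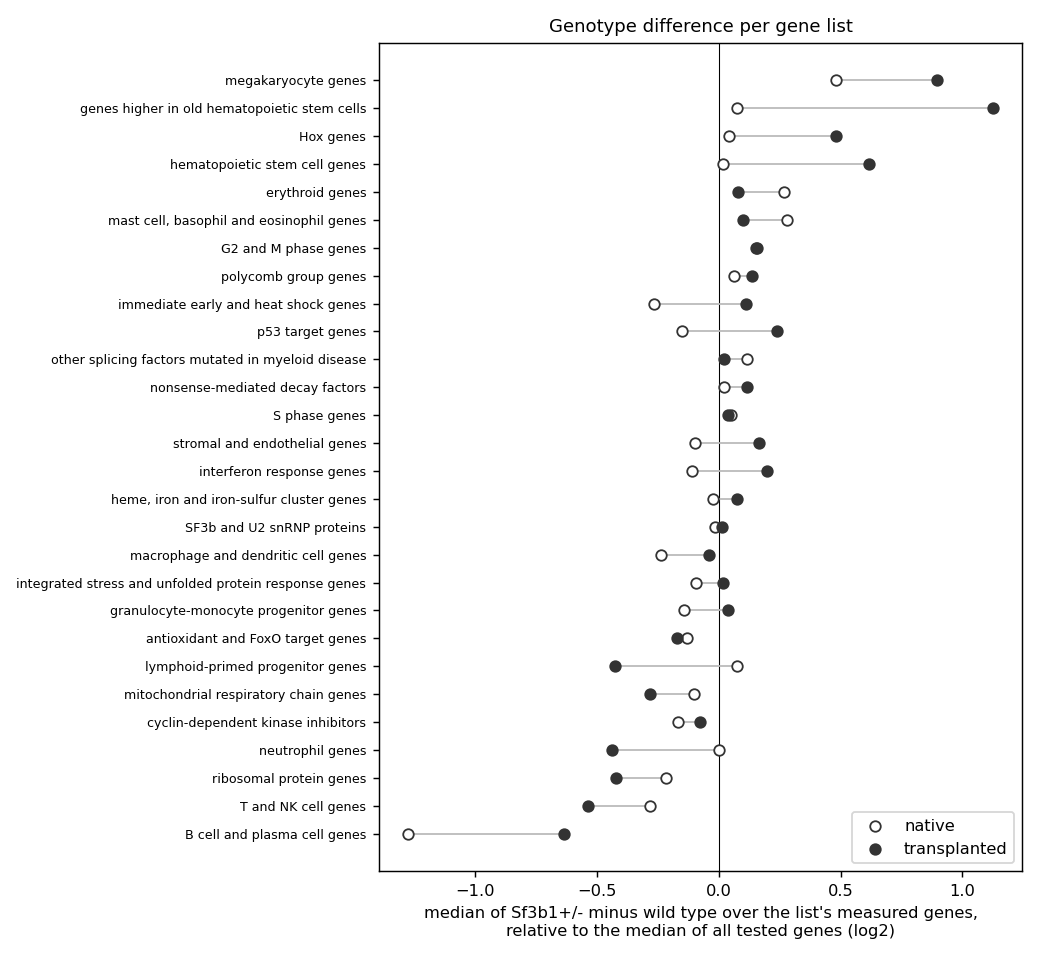
Median Sf3b1+/- minus wild-type difference (log2, horizontal axis) of each gene list with at least 5 measured genes, in native cells (open points) and transplanted cells (filled points), relative to the median of all compared genes. Megakaryocyte genes lie at 0.48 and 0.89, genes higher in old stem cells at 0.07 and 1.13, and B cell and plasma cell genes at -1.27 and -0.64; Hox genes, at 0.48 in transplanted cells, turn to -0.14 when genes close to background are included.

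The third comparison asks which genotype differences appear in both settings, the nearest thing to a repeat in this design. Higher in both was Ccn1 (NM_010516), a matrix-associated signalling protein, by 2.90-fold in native and 5.12-fold in transplanted cells. Ppbp (2.85-fold and 2.81-fold) and Gp1ba (2.19-fold and 2.28-fold) were joined by the transcription factor gene Mycn (2.36-fold and 2.58-fold), Gdf15, which encodes a stress-responsive cytokine (2.11-fold and 2.70-fold), Kcnj5 (1.93-fold and 7.50-fold) and Prss16 (1.92-fold and 2.24-fold). Among eosinophil genes Epx was higher by 2.23-fold and 3.42-fold, Rnase2a by 2.48-fold and 2.63-fold, Ear2 by 2.40-fold and 2.85-fold, Ear1 by 2.03-fold and 2.89-fold and Ear10 by log2 differences of 1.00 and 1.21, and the Ear and Rnase2a genes are close paralogs whose probes may read each other's transcripts.

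Lower in both settings were Klra16, an NK cell receptor gene of a large paralogous family, by 3.31-fold and 2.34-fold, and Bmp2, which encodes a bone morphogenetic protein, by 2.82-fold and 2.52-fold. Agrp (2.71-fold and 2.62-fold), Slamf7 (2.64-fold and 2.46-fold), Bcl2a1d (2.48-fold and 2.73-fold), Skil (2.48-fold and 2.02-fold), Xcl1 (2.34-fold and 2.10-fold) and Blnk (2.28-fold and 2.20-fold) followed. The remaining leading genes were Xkrx (2.13-fold and 2.18-fold), Crebrf (2.12-fold and 2.51-fold), Rnf224 (2.07-fold and 2.14-fold) and the dendritic and B cell gene Cd83 (2.07-fold and 2.67-fold). Bcl2a1d belongs to a family of near-identical copies. Heme, iron and iron-sulfur genes had medians of -0.02 (percentile 35.4) and 0.07 (percentile 85.1). Cyclin-dependent kinase inhibitors had medians of -0.17 (percentile 3.57) and -0.08 (percentile 29.2), with Cdkn1b at -0.34 and -0.51 and Cdkn1a at -0.91 and 0.14.

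Counted over all compared genes, 139 were at least 1.5-fold higher in both settings, against 33.0 if the native and transplanted lists were independent, and 201 were at least 1.5-fold lower in both, against 39.4. Quantile normalization gave 183 higher and 143 lower, cyclic loess 187 and 134, normexp 21 and 45, the filter on all 4 arrays 72 and 140, and spike-in scaling 852 and 30. Opposite directions were taken by 38 genes higher in native and lower in transplanted cells (27.2 if independent) and by 68 with the reverse (47.8). The numbers for independent lists do not allow for a technical difference that repeats in both settings. Before scaling, the 75th percentile of signal was higher on both Sf3b1+/- arrays than on their wild-type partners. It was 299.7 against 253 units in native and 430.3 against 292 in transplanted cells. Across genes, which are not independent replicates, the native and transplanted differences correlated with Pearson's r of 0.338 and Spearman's rho of 0.425, and 68.0% of genes had the same sign. The robust SD over genes was 0.278 for the mean genotype difference and 0.158 for the contrast between the settings' genotype differences, taken as their difference divided by 2 so that both contrasts are on the scale of a mean. Among the compared genes, 86 were well above background on both Sf3b1+/- arrays and on neither wild-type array, 72 of them with a bound above 1-fold, led by Myom1 (at least 1.96-fold higher), Snai1 (at least 1.75-fold), Fgd1 (at least 1.57-fold), Ercc6 (at least 1.52-fold) and Tcaim (at least 1.51-fold). The reverse held for 21 genes, led by Foxa1 (at least 2.32-fold lower), Fam228b and Tceanc (each at least 2.21-fold), Klra7 (at least 2.16-fold) and Ifnk (at least 2.11-fold). Such genes passed the filter only through the genotype where they are high, and they can also stand among the 139 and 201. The Sf3b1+/- arrays had more spots well above background, 48.7% against 47.7% in native and 51.5% against 50.2% in transplanted cells. The split of 86 to 21 was not separated from that difference.

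**Figure D2:**
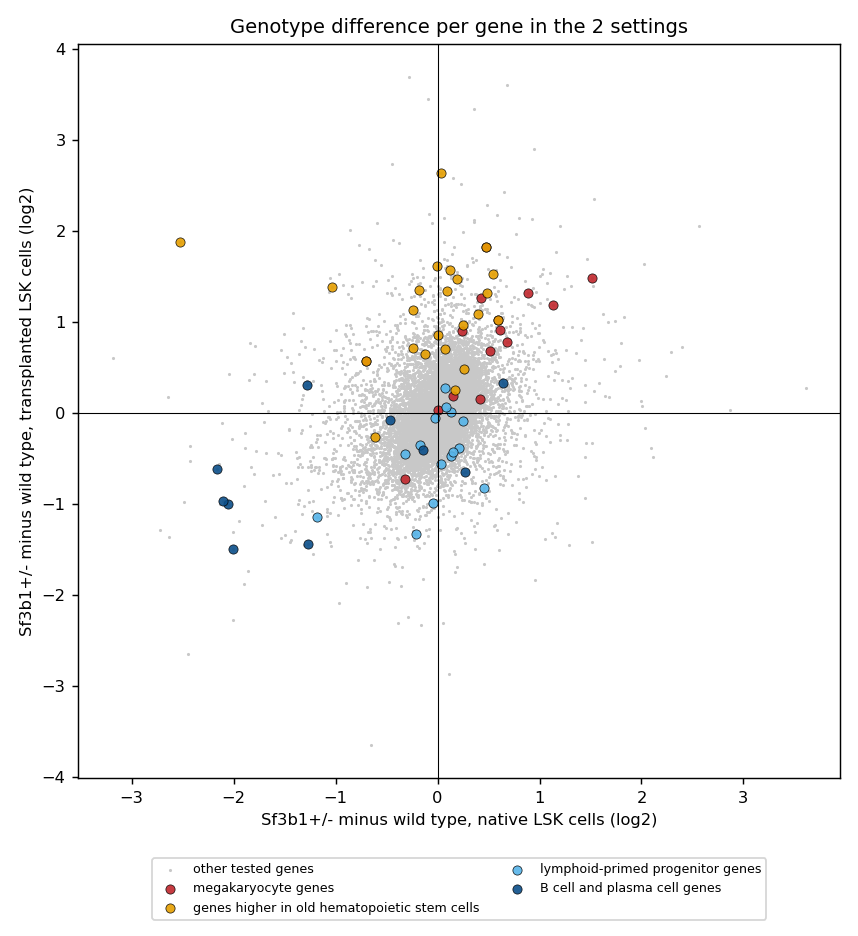
Sf3b1+/- minus wild-type difference of each compared gene (log2) in native cells (horizontal axis) and transplanted cells (vertical axis), with 4 gene lists in colour and 1 array behind each group. Megakaryocyte genes lie mostly to the upper right, B-lineage genes mostly to the lower left, and genes higher in old stem cells mostly above 0 on the vertical axis.

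A test of the genotype over both settings was made with limma, with the setting as a second term and 1 residual degree of freedom per gene. After Benjamini-Hochberg adjustment over all 13033 genes limma called 0 genes, with a smallest adjusted p of 0.309. An unadjusted p under 0.05 was reached by 1775 genes, where chance gives 652. A technical difference between the genotypes' arrays that repeats in both settings would also add to the 1775. Allowing the variance to follow the signal level, limma called 24 genes higher and 74 lower, and with spike-in scaling 456 and 27. Within the gene lists, fixed before the data were examined, limma called more. Each of the 29 lists was adjusted on its own, with no correction across lists. The list calls for the setting given below share that limit. Adjusted over the list alone, limma called 9 of 15 megakaryocyte genes higher and 1 lower, against 0 adjusted over all genes. Those called higher included Ppbp (adjusted p = 0.00355), Gp1ba (0.00497) and Gp5 (0.012). Of the 10 B cell and plasma cell genes limma called 5 lower and 1, Fcmr, higher adjusted over the list alone, with adjusted p of 0.019 for Igll1 and Vpreb3 and 0.044 for Vpreb1, while Ebf1, also called lower, and Fcmr were well above background on 2 arrays only. Adjusted over the list alone, limma further called 4 of 16 T and NK cell genes lower, among them Ccl5 and Il2rb (both 0.027), and Blnk lower among lymphoid-primed progenitor genes (0.010). Called higher were 3 of 11 erythroid genes, Hba-a2 (0.016), Hba-a1 (0.026) and Epor (0.038), the p53 target genes Gdf15 and Zmat3 (both 0.020), and Epx (0.018). Because the additive fit treats any difference between settings as error, it has little reach for effects seen in 1 setting, and its p-values measure the spread between these arrays alone.

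Whether genotype differences differ between the settings cannot be tested gene by gene with 1 array per group, and the lists give a description. Measured as transplanted minus native difference, 16 of the 29 lists had a median outside the central 95% of random lists, where random draws of genes give 1.45. That number does not hold for differences between samples, since genes of a list can move together and some lists share genes. In each setting alone, 13 lists lay outside that range in native and 15 in transplanted cells. Megakaryocyte genes and G2 and M phase genes were higher in both, and B cell, T and NK cell and ribosomal protein genes were lower in both, the last with the dependence on scaling given above. The p53, interferon and immediate early lists lay on opposite sides. The lists not placed outside the range in either setting were those of SF3b, nonsense-mediated decay, heme and iron, and cyclin-dependent kinase inhibitors, together with granulocyte-monocyte progenitor genes (-0.14 and 0.04), stromal and endothelial genes (-0.10 and 0.16), stress and unfolded protein response genes (-0.09 and 0.02), polycomb group genes (0.06 and 0.14) and antioxidant and FoxO target genes (-0.13 and -0.17).

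**Figure D3:**
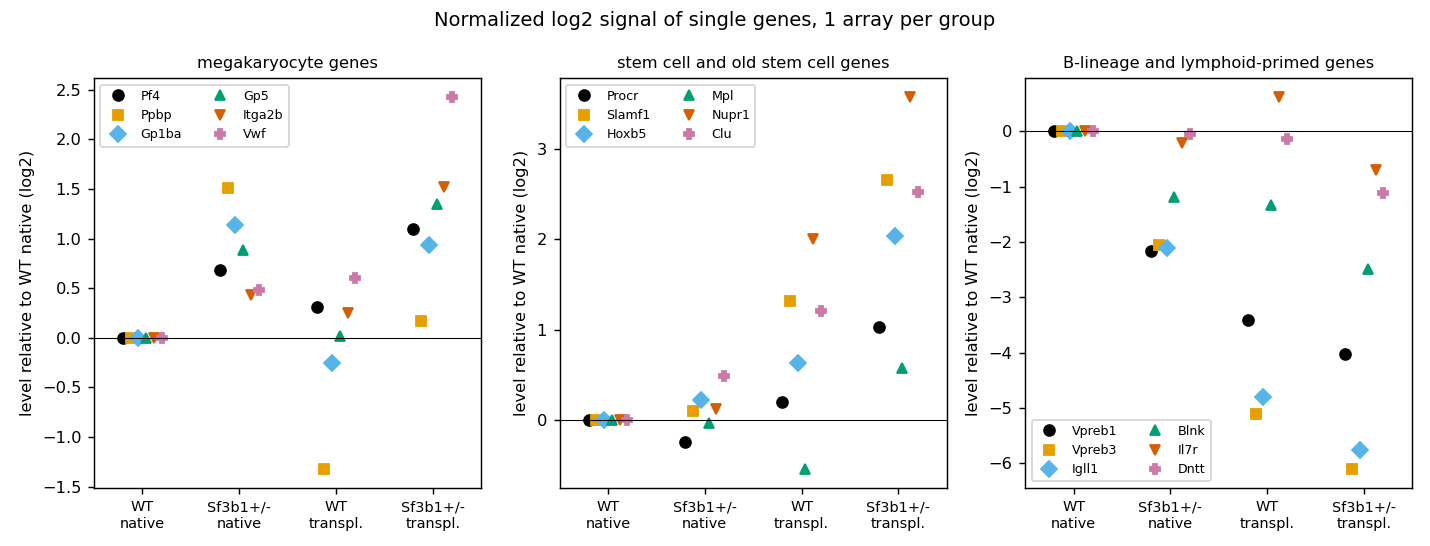
Normalized log2 signal of single genes relative to wild-type native cells (vertical axis) in the 4 groups, 1 point per array and gene, for megakaryocyte genes, stem cell genes and B-lineage or lymphoid-primed genes picked from the lists for display after the values were seen. Slamf1 is 1.34 higher in Sf3b1+/- than in wild-type transplanted cells but 0.09 higher in native cells, and Igll1 is 4.30-fold lower in native Sf3b1+/- cells than in wild type and lower still in both transplanted groups.

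The last comparison sets transplanted against native LSK cells over both genotypes, which differ at once in age, in transplantation and in the recipient's irradiated marrow. Early B-lineage genes were far lower after transplantation. Vpreb3 fell by 5.11 in wild-type and 4.05 in Sf3b1+/- cells on the log2 scale (limma, Benjamini-Hochberg adjusted p = 0.0384), Igll1 fell by 4.80 and 3.65 (0.0398), Pou2af1, a B-cell co-activator gene, fell by 2.52 and 2.35 (0.0384), and Rag1, which encodes a recombinase of antigen receptor genes, fell by 2.02 and 2.14 (0.0384). The B cell and plasma cell list had medians of -2.60 and -1.80, below all random lists, and 6 of its 10 genes were lower adjusted over the list alone, against 4 over all genes. Genes higher in old stem cells had medians of 0.82 in wild-type and 2.10 in Sf3b1+/- cells, above all random lists, with 21 of 23 called higher adjusted over the list alone and 2, Clca3a1 and Gpr183, over all genes. Nupr1 stood at 2.01 and 3.46, and Jam2 was 4.91-fold and 12.7-fold and Sult1a1 3.78-fold and 11.6-fold higher.

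The class II histocompatibility genes H2-Eb1 and H2-Aa rose with transplantation. H2-Eb1 rose 3.84-fold and 3.54-fold (limma, adjusted p = 0.0386) and H2-Aa 3.33-fold and 3.99-fold (0.0398), and macrophage and dendritic cell genes had medians of 0.98 and 0.94, above all random lists, with 7 of 11 called adjusted over the list alone and 2 over all genes. On the log2 scale Tm4sf1 rose by 4.16 and 4.90 (limma, adjusted p = 0.0361), Upb1 by 3.04 and 3.08 (0.0332), Lgals3, which encodes galectin-3, by 2.78 and 2.97 (0.0338), Aif1 by 2.36 and 2.61 (0.0384), Clca3a2 by 2.53 and 3.00 (0.0384), the tight junction gene Cldn5 by 2.99 and 2.45 (0.0386) and Ccn1 by 2.78 and 3.60 (0.0398). Sparc fell 8.40-fold and 10.5-fold (limma, adjusted p = 0.0338), and on the log2 scale Itgb5 fell by 2.15 and 2.63 (0.0398) and Cpe by 1.75 and 2.13 (0.0481). Lbhd2 (2.36 and 3.29, adjusted p = 0.0552), Csprs (2.23 and 3.25, 0.0594), Gfra2 (-5.06 and -3.39, 0.0594), Jam2 (0.0737), Rftn2 (-2.25 and -3.63, 0.0752) and Vpreb1 (-3.41 and -1.86, 0.0924) did not pass in limma despite their size. Cdkn2a, a locus of cell cycle inhibitors whose probe was not assigned to a single product, passed with an adjusted p of 0.0361 in limma but was well above background on 2 arrays, so no fold is given.

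Cell cycle genes of mitosis were lower after transplantation, with G2 and M phase medians of -0.48 and -0.43, below all random lists, and 20 of 38 genes lower adjusted over the list alone against 0 over all genes. Mki67 stood at -0.79 and -0.82, Plk1 at -0.90 and -0.83 and Cenpe at -0.92 and -1.04. S phase genes had medians of -0.05 and -0.08. Lymphoid-primed progenitor genes had medians of -0.17 and -0.75, with 4 of 15 lower adjusted over the list alone, among them Flt3 (-0.61 and -1.20). Granulocyte-monocyte progenitor genes had medians of 0.29 and 0.50, with Irf8 at 1.17 and 1.28 and Lyz2 at 0.82 and 1.86, and interferon response genes 0.21 and 0.50, with Ifit1 at 1.26 and 1.22. Hox genes had medians of 0.51 and 0.71, which were 0.13 and 0.38 over the genes well above background on all 4 arrays and -0.08 and -0.16 with genes close to background included. Stress and unfolded protein response genes had medians of 0.12 in wild-type and 0.59 in Sf3b1+/- cells, with Atf3 at 0.76 and 1.65, and polycomb group genes -0.23 and -0.26.

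Over all genes limma called 55 higher and 20 lower in transplanted cells (Benjamini-Hochberg 0.05, smallest adjusted p 0.0332), with 3357 at an unadjusted p under 0.05. The calls sit close to the threshold: quantile normalization and cyclic loess called 0 genes, with smallest adjusted p of 0.0646 and 0.0507, whereas normexp called 494 higher and 556 lower, the authors' deposited ratio values 4 and 3, and spike-in scaling 7654 and 91. By size, 593 genes were at least 1.5-fold higher in transplanted cells of both genotypes, against 118 if the genotypes were independent. At least 1.5-fold lower were 319, against 52.5, and across genes the setting differences of the genotypes correlated with r of 0.646. The numbers for independent genotypes do not allow for a technical difference that repeats in both. Signal before scaling was higher on both transplanted arrays than on the native array of the same genotype.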

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

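The tests that weigh explanations in this part were chosen after the results were seen, while the gene lists were fixed before the data were examined.

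Genes of hematopoietic stem cells were higher in transplanted Sf3b1+/- than in transplanted wild-type LSK cells. A trend of the differences with signal is argued against, since cyclic loess, which removes such trends, left a stem cell list median of 0.58. Low signal of these genes on the wild-type transplanted array stays open, since their list lay 0.038 above wild-type native cells there (percentile 67.3 of random lists) and the setting itself may move it. More megakaryocyte-lineage cells in the sort cannot be told apart either: 11 megakaryocyte genes outside the stem cell lists had a median of 0.90 in this comparison and exceeded their native difference by 0.10, against 0.53 over 23 stem cell genes, a gap of 0.43 with a bootstrap SE over genes of 0.19. A larger share of stem cells within the sorted fraction stays open as well. The lymphoid-primed list stood at -0.43 in the same comparison, as a larger share could give. Granulocyte-monocyte progenitor genes (0.04, percentile 83.5) and G2 and M phase genes (0.15, percentile 98.7) were not lower there, so these lists do not decide it. Higher expression per cell, chance differences between recipients and the position of the array stay open with 1 array per group.

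As a list, genes of the B lineage were lower in Sf3b1+/- LSK cells, though not every member was. A trend with signal is argued against by the native B cell list median of -1.22 after cyclic loess. Fewer cells of the pro-B stage in the native Sf3b1+/- sort could give the pattern and would also lower Il7r, Rag1 and Rag2, but these went both ways in native cells (-0.21, -0.32 and 0.21, with a median of -0.21), so this cannot be told apart from lower expression per cell. The sort was made to remove cells with lineage markers, but its purity was not tested here. Early precursors and other cells left in the sort both stay possible as the source. A difference in age or health between the mice was not tested.

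Probes named by genome position, which matched no gene symbol and enter no comparison of named genes, were lower in Sf3b1+/- cells relative to probes of protein-coding transcripts. Whether they lie within known genes was not tested. Over 4163 probes named by genome position the median genotype difference over both settings lay at -0.21 relative to that of 15436 probes of protein-coding transcripts, with -0.12 in native and -0.30 in transplanted cells, and at -0.12 over both settings with normexp. The gap was not particular to them: it was -0.22 for AK cDNAs, -0.18 for other RefSeq transcripts, -0.15 for Ensembl transcripts and -0.14 for other unmatched probes. With spike-in scaling, position-named probes had medians of 0.14 in native and 0.21 in transplanted cells, below 0.26 and 0.52 for coding probes. A trend with signal is argued against by a gap of -0.18 for position-named probes after cyclic loess, with a bootstrap SE of 0.0063 over 500 draws of probes. That SE holds no spread between arrays or mice. A constant added signal such as genomic DNA in the wild-type samples is argued against by a median of -0.21 in the brightest of 5 equal bins of position-named probes, against -0.22 in the dimmest. Arrays of higher total signal could read these probes lower, and here the gap from native to transplanted arrays was -0.067 in Sf3b1+/- but 0.10 in wild-type cells, so the explanation cannot be told apart from a genotype effect. Differences in RNA quality or amplification between genotypes also stay open.

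Among 8901 probes without a gene symbol that were well above background on all 4 arrays, 265 were at least 1.5-fold lower in Sf3b1+/- cells of both settings and 43 at least 1.5-fold higher. These counts were 187 lower and 64 higher with quantile normalization, 178 and 63 with cyclic loess, 50 and 16 with normexp, and 29 and 315 with spike-in scaling, which moves all genes up as given for the comparisons. The genotype difference of p53 target genes had opposite signs in the settings, with a list median of the transplanted minus native difference of 0.31, and this was not tested. The same held for interferon response genes, at 0.23, and for immediate early and heat shock genes, at 0.35, neither of which was tested.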

How the results depend on the processing

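Cyclic loess and the use of every probe were chosen after results were seen, and the other alternatives were planned. No paired analysis was possible because the groups share only 1 replicate number. Of the values of named genes under alternatives 4206 kept within the spread, 788 moved and 6 reversed. Of those of gene lists 1009 kept, 29 moved and 6 reversed. Of the design's results 116 kept, 50 moved, 4 became stronger and 10 weaker. Many labels of named genes were set by construction. Filters leave a gene's own value unchanged. The percentile over all probes and the deposited ratio values shift whole arrays, by less than the spread of 0.22. Spike-in scaling shifts every gene's differences by more than that spread. The counts for named genes therefore say little about robustness. With normexp, 8 genes were at least 2-fold higher and 25 lower in native cells, 91 and 24 in transplanted cells, and 21 and 45 were shared. The offset of 50 shrinks differences by construction. With normexp the setting test also called 494 and 556, and the ribosomal protein list for setting in Sf3b1+/- turned from -0.07 to 0.13. The cause of these 2 changes was not tested, and this alternative includes quantile normalization. With quantile normalization the setting test called 0 higher and 0 lower and the ribosomal protein list for setting in Sf3b1+/- turned to 0.086; the cause was not tested. With spike-in scaling, native counts were 242 and 91, transplanted 1416 and 28, shared 852 and 30, genotype calls 456 and 27, setting calls 7654 and 91, and the Sf3b1 differences -0.15 and 0.40. That scaling moves the median of all genes by 0.25, 0.51, 0.49 and 0.75 for the native, transplanted, wild-type setting and Sf3b1+/- setting differences, which also turned the Sf3b1+/- setting differences of Hif1a (0.14), Il5ra (0.11), Pcgf5 (0.16), Rnf224 (0.011) and Upf3b (0.11). With the deposited ratio values the setting test called 4 and 3; the cause was not tested. With genes well above background on all 4 arrays, native counts were 27 and 76, 95 transplanted genes were lower, 72 were shared higher and setting calls were 190 and 70, with fewer genes tested. Without a filter, native counts were 420 and 739, transplanted 694 and 876, shared 298 and 522, setting calls 0 and 0, and the correlation of the genotype differences 0.1996, while the Hox list turned to -0.14 in the transplanted comparison, -0.082 for setting in wild type and -0.16 in Sf3b1+/-, and the ribosomal protein list for setting in Sf3b1+/- to 0.064; genes near background are added by construction. With the median over probes setting calls were 0 and 0 and Kdr in transplanted cells turned to 0.43, since its probes differ. With cyclic loess setting calls were 0 and 0; the cause was not tested. With every probe, native counts were 373 and 541, transplanted 459 and 643, shared 285 and 658, and setting calls 0 and 0, with more features tested. At 1.5-fold, 423 and 613 native and 1016 and 837 transplanted genes were counted, and at 2-fold in both settings 23 and 31, by construction. With a variance trend limma called 24 and 74 for genotype and 1172 and 1050 for setting, with robust settings 11 lower for setting, and with setting alone in the model 24 and 8; the cause was not tested. The smallest adjusted p of limma for genotype ranged over the alternatives from 0.000314 to 0.459, and for setting from 3.59e-07 to 0.171. Without 1 array the mean Sf3b1 difference ranged from -0.41 to -0.11. Signal over background limits lists such as the B cell list, with 6 of its 10 compared genes well above background on all 4 arrays, and the Hox list, with 12 of 17. With normexp, list medians also came nearer to 0 for neutrophil genes in transplanted cells (-0.26), Hox genes in transplanted cells (0.25), and mast cell, basophil and eosinophil genes (0.16) and macrophage and dendritic cell genes (-0.16) in native cells, and with quantile normalization for native immediate early and heat shock genes (-0.14).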

Other observations

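No test was run in this part, and the stretch described was chosen after its values were seen. A stretch of mouse chromosome 13, from 108548345 to 108679004 on build mm9 in the reverse orientation, is covered by 6 probes named by genome position. Of the 4 that were well above background on all 4 arrays, 3 were lower in Sf3b1+/- cells of both settings, by 2.62-fold, 4.89-fold and 5.66-fold in native cells and by 2.99-fold, 3.20-fold and 3.25-fold in transplanted cells. The other, the brightest of the stretch, was lower by 1.16-fold and 1.11-fold. The remaining probes were well above background on 2 arrays, so no fold is given for them. What is transcribed there is not given in the sources used here.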
